A study of Rattus norvegicus with 12 samples.

How the data were processed

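RNA from cultured preadipocytes was measured on 12 one-colour expression arrays, 1 array per fat depot and rat. Perirenal and epididymal fat came from 3 rats aged 3 months (young) and 3 rats aged 30 months (old), which gave 4 groups of 3 arrays. Per the labels, the animals were male Brown Norway rats, stromal cells were freed from each fat pad by collagenase, plated, replated and grown to confluence, and RNA was extracted with TRIzol and labelled with biotin from an oligo-dT primer. The labels also state that macrophage markers in these cultures did not differ with age or depot. Dates and labelling batches are not given in the sources used here. The 3 arrays per group limit the precision of every value.

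The deposited values were intensity values, with 1 signal per probe set and array on a linear scale, and the authors' processing notes name MAS5 without a version or parameters. The mean of each array, with the lowest and highest 2% of signals left out, lay between 500.1 and 500.2, so the deposited scaling was kept. Detection calls, image files and probe positions were not used here. Signals were put on the log2 scale without an offset, and 2 signals of 0 were set to the lowest positive signal of 0.1.

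The table held 15923 probe sets. The 57 array control probe sets were left out of the comparisons and were used to describe the arrays. Probe sets in the lowest 30% of mean log2 signal over all 12 arrays were left out, which corresponds to a geometric mean signal of 56.3, and 11106 probe sets were tested. A table of probe sets and genes gave exactly 1 symbol for 12783 probe sets, several for 312 and none for 2771. Of the tested probe sets, 9346 had exactly 1 symbol, and these stood for 8002 genes.

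Differences were tested with limma 3.58.1 in R 4.3.3: a linear model with 1 term per group on all 12 arrays, moderated with an intensity trend, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Depot differences are perirenal minus epididymal and age differences are old minus young. The comparisons were the depot difference averaged over ages and within each age, the age difference within each depot and averaged over depots, and the age by depot interaction (the age difference in perirenal cells minus that in epididymal cells). For the age difference averaged over depots the mean log2 signal of both arrays of a rat was used, 3 rats against 3, since arrays of 1 rat are not independent. Errors beside log2 differences are standard errors from limma. Counts at an unadjusted p under 0.05 are descriptive, since a share of 0.05 of the tested probe sets is expected to reach it without any difference. Fits with the rat as a fixed or random block were alternatives, since the sources used here do not say that the study blocked by animal. The labelled pairing was checked on the deviations from the group means, whose correlation across probe sets was 0.0393 to 0.201 between arrays of a rat. For each of the 6 rats the best match was its own other array.

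The 23 gene lists were written before the data were examined: adipogenic regulators, adipocyte and lipid storage genes, inhibitors of adipogenesis, inflammatory and secretory genes, cell cycle arrest and p53 targets, proliferation, extracellular matrix, developmental patterning genes, mesothelial markers, macrophage and leukocyte markers, endothelial markers, smooth muscle and contractile markers, adrenocortical with renal and epididymal epithelial markers, Schwann cell and neural markers, skeletal muscle and erythroid markers, heat shock and unfolded protein response, oxidative stress and detoxification, mitochondrial oxidative phosphorylation, interferon response and antigen presentation, complement, the insulin-like growth factor axis, TGF-beta and BMP signalling, and cholesterol synthesis. They held 786 symbols, of which 639 were matched to the array. Each list was tested with limma's camera at a preset correlation of 0.01 on the probe set with the highest mean signal of each gene, with adjustment over the 22 lists that had at least 5 measured members. The estimated correlation was run beside it. Members past the threshold were counted over all tested probe sets and also adjusted over the list alone.

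Named genes followed a rule set before the data were examined. For the depot difference averaged over ages and for age within each depot these were the 8 largest rises and 8 largest falls past the threshold whose groups did not overlap, or the 4 smallest p in each direction where fewer than 5 genes passed. For the other comparisons they were the 3 largest in each direction, or the 2 smallest p where none passed. Up to 4 members of each list past the threshold with the smallest p were added, or the 2 with the smallest p as values where none passed. Pparg, Cebpa, Fabp4, Tnf, Il6, Ddit3, Celf1 and Dlk1 were included in the depot difference averaged over ages and in age within each depot, where they were tested, and genes named outside the rule are marked in the text.

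The fits were tested on simulated data of the same design, with 100 probe sets changed by each of 2 sizes. A log2 change of 1 was recovered in 31 (interaction) to 76 (depot averaged over ages) of them and a log2 change of 2 in 72 to 96, with 1 to 7 false calls per comparison. The simulated noise was independent between probe sets and arrays. These counts therefore do not cover correlated genes, rat effects or array-wide structure. They also do not cover comparisons in which fewer probe sets change, where the adjustment is stricter and recovery lower. Alternatives set before the data were examined were quantile normalization, an offset, a floor under the signals, no filter, a filter at 50%, no intensity trend, array weights, only the groups compared, 1 probe set per gene, the rat as a block, and leaving out each array or rat in turn. After the control probe sets had been seen, 3 more were added: the log2 ratio of the 3' to the 5' beta-actin signal of each array as a covariate, leaving out the 2 arrays with the highest such ratio (epididymal old 2 and epididymal young 3), and counting only genes whose several probe sets were all past the threshold in 1 direction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.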

Results

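Expression was measured in preadipocytes, the fat cell precursors of the stromal fraction, grown to confluence from perirenal and epididymal fat of 3 young and 3 old rats. The 12 arrays were 3 each of young perirenal, old perirenal, young epididymal and old epididymal cells. The design asks how the cells differ between depots, how they differ with age, and whether the age difference depends on the depot. The median signal of all probe sets was 194.6 to 202 on the perirenal arrays and 153 to 176 on the epididymal arrays. Across probe sets, which are not independent replicates, arrays of 1 depot and age had a mean correlation of 0.965 in perirenal and 0.95 in epididymal cells. The first principal component held 59.3% of the variance and separated all perirenal from all epididymal arrays.

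Some control probe sets also moved with depot. The ratio of the 3' to the 5' signal of beta-actin, a measure of how complete the labelled RNA is, was 0.902 to 1.11 on the 6 perirenal arrays and 5.25 to 55.0 on the 6 epididymal arrays. That of Gapdh was 1.06 to 1.17 and 1.85 to 6.94. The bacterial transcript dap, a poly(A) control added to RNA before labelling, had a signal of 1.08 ± 0.688 (SD, n = 6 arrays) on perirenal and 645 ± 97.7 (SD, n = 6 arrays) on epididymal arrays. Depot and these controls therefore separated the same arrays, so no comparison of depots within a set of like controls could be made.

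**Figure D1:**
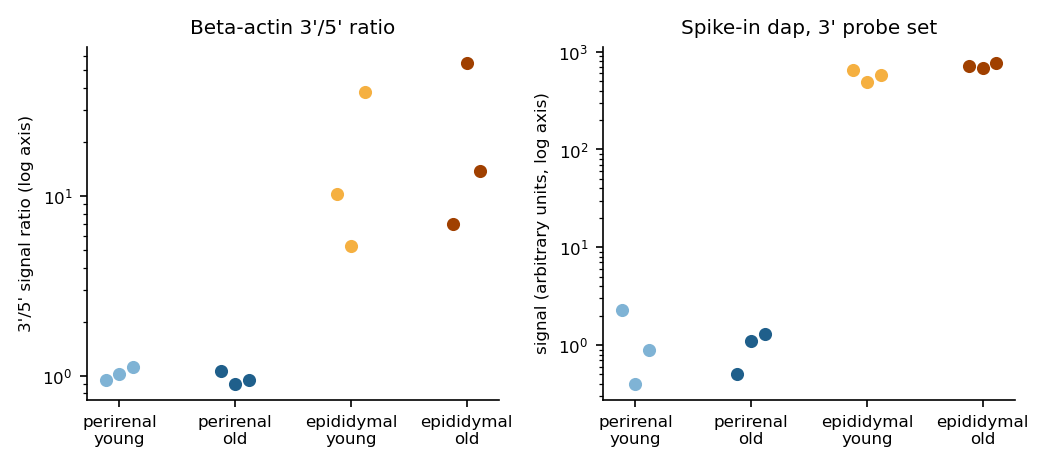
The beta-actin 3'/5' signal ratio and the signal (arbitrary units) of the spike-in dap on log axes for each of the 12 arrays, with 3 points per group. All epididymal arrays lay above all perirenal arrays in both, with ratios of 5.25 to 55.0 against 0.902 to 1.11.

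Between depots, genes of matrix and contractile tissue were lower in perirenal cells. Mfap4, which codes for a microfibril-associated glycoprotein, was 10.8-fold lower (log2 difference -3.43 ± 0.15 SE, n = 6 arrays per depot, adjusted p = 4.72e-08). Actg2, the enteric smooth muscle actin, was 6.2-fold lower (-2.63 ± 0.21). Of 52 measured extracellular matrix genes 39 fell, 7 rose and 6 did not pass, among them Tnc (tenascin C, -1.73 ± 0.12), Loxl1 (a lysyl oxidase that cross-links elastin, -1.22 ± 0.10) and Bgn (biglycan, -1.06 ± 0.09). Adjusted over the list alone, 39 fell and 8 rose, the list median was -0.71, and the camera adjusted p was 1.5e-09 (adjusted p = 0.0219 with an estimated correlation). Of the 17 matrix genes with several tested probe sets, 8 had all of them past the threshold, and all 8 were lower in perirenal cells. These were chosen after their values were seen and include the collagens Col1a1, Col1a2, Col5a2, Col6a2 and Col14a1. Smooth muscle and contractile markers fell in 17 of 21 and rose in 1, with the same counts adjusted over the list alone, such as Tpm2 (tropomyosin, -1.93 ± 0.13), Mylk (myosin light chain kinase, -1.60) and Smtn (smoothelin, -1.21). Their median was -1.20 and their adjusted p 4.64e-07, against an adjusted p = 0.267 with an estimated correlation. None of the 4 contractile genes with several probe sets had all of them past the threshold in 1 direction. The beta-actin 3'/5' ratio (0.902 to 1.11 against 5.25 to 55.0) moved with depot alongside both lists.

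The other large differences between depots included receptors, enzymes and growth factors. Lower in perirenal cells were Olr1, a receptor for oxidised low density lipoprotein (-3.88 ± 0.31), Tgm2, the tissue transglutaminase (9.81-fold, -3.29 ± 0.28), Ptn, the heparin-binding growth factor pleiotrophin (8.15-fold, -3.03 ± 0.29), and Aldh1a2, which makes retinoic acid (7.65-fold, -2.94 ± 0.26). A further probe set of Tgm2 differed by -2.11. Higher in perirenal cells were Fgf7, a fibroblast growth factor that acts on epithelium (15.7-fold, 3.97 ± 0.29), Il1r1, the interleukin 1 receptor (3.64 ± 0.44, 3.02 in its other probe set), and Cd14, a co-receptor for lipopolysaccharide (7.22-fold, 2.85 ± 0.14). The largest rises under the rule for named genes were those of Vof16 (4.90 ± 0.64) and Lyst (a regulator of lysosome traffic, 4.54 ± 0.51). No fold is given for Vof16, Lyst, Il1r1 and Olr1, since the lower group lay below the filter level of 56.3, near background, and the size of the log2 difference there is not well measured. The epididymal geometric means (young and old) were 15.3 and 9.0 for Vof16, 7.5 and 24.1 for Lyst and 22.7 and 90.0 for Il1r1, and the perirenal ones were 45.0 and 42.2 for Olr1. The dap spike-in signal (1.08 against 645) separated the same arrays. With the 3'/5' ratio as a covariate the differences were -4.18 for Mfap4, 2.49 for Cd14 and 2.71 for Fgf7, all past the threshold, 1.44 for Il1r1 and 1.26 for Lyst. The ratio nearly coincides with depot, so depot values from this fit rest on the slope among the epididymal arrays and are imprecise.

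Developmental patterning genes rose in 16 and fell in 4 of 27, with the same counts adjusted over the list alone and a median of 0.81. They include the homeobox genes Hoxa10 (3.55 ± 0.41) and Prrx1 (10.1-fold, 3.33 ± 0.28, with 5.50 in its other probe set) and the mesodermal factor Twist1 (3.47 ± 0.67). Twist1 and Hoxa10 also lay below the filter level in epididymal cells, so no fold is given, and with the 3'/5' covariate the Twist1 difference was -0.89. Nr2f2, a nuclear receptor of mesenchymal patterning, had probe sets at -1.39 and 1.24, and Wt1, a marker of mesothelium, at -1.64 and 0.93, each past the threshold in both directions. Proliferation genes rose in 21 and fell in 1 of 44 (23 and 1 adjusted over the list alone), with a median of 0.53. Examples are Birc5 (survivin, 1.36), Tyms (thymidylate synthase, 1.25) and Ccnd1 (cyclin D1, 1.12, and 1.40 and 1.24 in its other probe sets). Interferon and antigen presentation genes rose in 14 and fell in 3 of 32 (15 and 3 adjusted over the list alone, median 0.41). Ifit1, an interferon-induced gene (2.09 ± 0.29), the class II gene RT1-Da (1.63) and its transactivator Ciita (1.46, with an old epididymal mean below the filter level) were among them, and in epididymal cells Ifit1 and RT1-Da at both ages and Ciita in old rats lay below the filter level. Cholesterol synthesis genes rose in 8 and fell in 1 of 19, also adjusted over the list alone, with a median of 0.39, such as Lss (lanosterol synthase, 1.10, and 1.79 in its other probe set) and Sc5d (sterol desaturase, 1.10, but 0.21 with adjusted p = 0.219 in its other probe set). Heat shock and unfolded protein genes fell in 10 and rose in 1 of 31 (8 and 1 adjusted over the list alone, median -0.21), such as Hspb1 (a small heat shock protein, -0.96) and Pdia3 (a disulfide isomerase, -0.72, but 0.16 with adjusted p = 0.469 in its other probe set). The 3'/5' ratio and the spike-ins moved with depot beside each of these lists as well.

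The camera adjusted p was 0.000907 for proliferation, 0.0364 for patterning, interferon and heat shock genes, and 0.0402 for cholesterol synthesis. None of these held with an estimated correlation: adjusted p = 0.72 with an estimated correlation for proliferation and for cholesterol synthesis, 0.141 for patterning and heat shock, and 0.441 for interferon genes. After quantile normalization the adjusted p was 0.0979 for patterning and 0.452 for heat shock genes. With the 3'/5' covariate it was 0.102 for both, and 0.274 for interferon genes, and without the filter 0.0638 for patterning and 0.0676 for cholesterol synthesis. Leaving out 1 rat ended further calls: patterning without young rat 2 (0.0578) or old rat 3 (0.0781), heat shock and interferon genes without old rat 3 (0.0939 each), and cholesterol synthesis without young rat 1 (0.057), old rat 1 (0.103) or old rat 2 (0.0508).

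**Figure D2:**
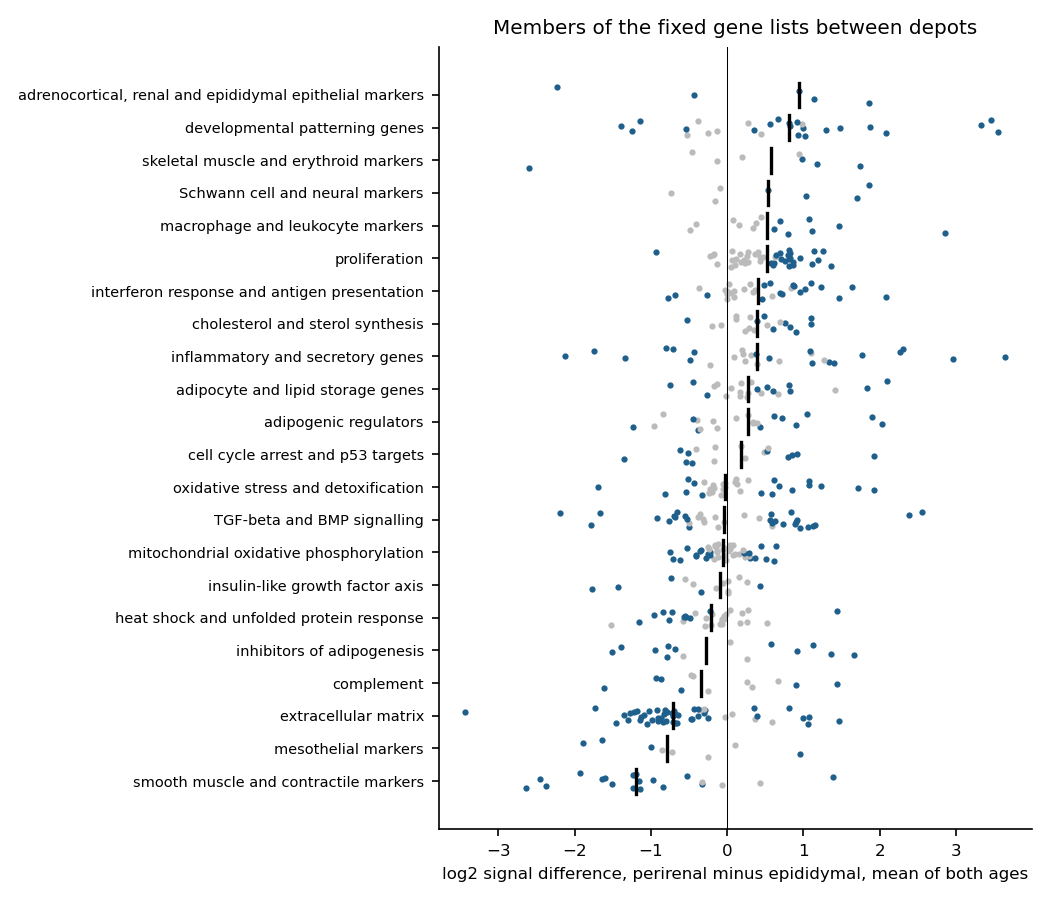
Log2 signal differences, perirenal minus epididymal and averaged over ages, for the measured members of each list with at least 5 (points, blue where past the threshold), with the list median as a bar. The medians of smooth muscle (-1.20) and matrix genes (-0.71) lay below 0 and those of proliferation (0.53) and patterning genes (0.81) above it.

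Genes of fat cell identity moved in both directions. Adipogenic regulators rose in 7 and fell in 3 of 21 and lipid storage genes in 7 and 3 of 23, and neither list passed (adjusted p = 0.541 and 0.299). Adjusted over the list alone, the counts were 7 and 3, and 6 and 3. Slc2a4, the insulin-responsive glucose transporter, was higher in perirenal cells (2.10 ± 0.26, 1.47 in its other probe set), as was Rxra, a nuclear receptor that pairs with Pparg (1.90, with an old epididymal mean of 22.2, below the filter level). Pparg itself, the central adipogenic receptor, differed by 0.12 ± 0.26 (adjusted p = 0.72, and -0.21 after quantile normalization), Fabp4, the adipocyte fatty acid binding protein, by 1.42 ± 0.74 (0.12), and Celf1, an RNA-binding regulator of translation, by 0.26 ± 0.11 (0.068, and 0.30 in its other probe set). Ddit3, which codes for the stress factor CHOP, differed by -0.58 ± 0.24 (0.055), and the adjusted p was 0.0115 with the rat as a fixed block, 0.0383 as a random block and 0.0152 after quantile normalization. For Fabp4 it was 0.0339 with the fixed block, 0.0952 with the random block and 0.366 after quantile normalization. Il6, the cytokine interleukin 6, differed by 0.09 ± 0.34 (0.832), and by -0.11 to 0.50 with 1 rat left out. Cebpa, Tnf and Dlk1 lay below the signal filter. Inhibitors of adipogenesis rose in 5 and fell in 6 of 14 (6 and 7 adjusted over the list alone, adjusted p = 0.541), among them Gata2, a blood and precursor cell factor (-1.50).

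Markers of other cell types were mixed. Macrophage and leukocyte markers rose in 7 of 14 and fell in none, also adjusted over the list alone, with a median of 0.53 and an adjusted p of 0.0671. The adjusted p was 0.0384 with the rat as a block and 0.0343 without the 2 arrays with the highest 3'/5' ratio, but 0.221 after quantile normalization, 0.105 without the filter, 0.226 with the 3'/5' covariate, and adjusted p = 0.72 with an estimated correlation. Endothelial markers rose in 3 of 4 and Schwann cell and neural markers in 4 of 7 (adjusted p = 0.321), with the same counts adjusted over the list alone, and S100b, a calcium-binding protein of glia and adipocytes, was among the latter (1.86). Mesothelial markers fell in 3 and rose in 1 of 8 (adjusted p = 0.133), skeletal muscle and erythroid markers rose in 3 and fell in 1 of 8 (0.541), and adrenocortical, renal and epididymal markers rose in 3 and fell in 2 of 5 (0.992). Star, which carries cholesterol into mitochondria for steroid synthesis, was lower in perirenal cells (-2.23 ± 0.22, -0.94 in its other probe set). The 3'/5' ratio moved with depot here too.

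Secreted and signalling genes included Plat, the tissue plasminogen activator (-1.74 ± 0.11), Icam1, an adhesion molecule (-1.34), and Igf1 (insulin-like growth factor 1, -1.78 ± 0.24, -1.86 in its other probe set). Also among them were Bmp6, a bone morphogenetic protein (-1.79, and -0.92 in its other probe set), Smad6, an inhibitor of that pathway (2.39 ± 0.18), Tgfbr3, the betaglycan receptor (2.56 ± 0.19, and 2.18 in its other probe set), and Gstm2, a glutathione transferase (1.72). Their lists did not pass. Inflammatory genes rose in 11 and fell in 7 of 28 (adjusted p = 0.529), TGF-beta and BMP genes in 15 and 11 of 37 (0.976), and insulin-like growth factor genes in 1 and 4 of 14 (0.297). Oxidative stress genes rose in 10 and fell in 6 of 32 (0.80), oxidative phosphorylation genes in 8 and 12 of 45 (0.426), complement genes in 2 and 4 of 12 (0.541), and arrest and p53 genes in 5 and 5 of 17 (0.976). Adjusted over the list alone, the counts were 15 and 12 for TGF-beta genes, 7 and 10 for oxidative phosphorylation, 6 and 5 for arrest genes, and unchanged for the other 4 of these lists. The median, mean and test differed in sign for TGF-beta genes (median -0.04, mean 0.11) and oxidative stress genes (-0.03 and 0.16), both tested upward, and for arrest genes (0.18 and 0.13), tested downward.

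Over all tested probe sets, 5738 of 11106 differed between depots in the average over ages, 3357 higher and 2381 lower in perirenal cells, with limma and Benjamini-Hochberg adjustment. Of these, 1787 differed more than 2-fold, 1365 of them higher. With the rat as a fixed block 5754 passed. Quantile normalization moved the median of all probe sets from 0.08 to -0.03 and the share of calls that were higher in perirenal cells from 58.5% to 46.9%, so differences near this shift in size have no settled direction. The list medians given above for matrix, contractile, patterning and proliferation genes were farther from 0 than this shift of the median. The shift depends on signal level, however: mean lower quartiles were 59.95 on perirenal and 38.54 on epididymal arrays, and mean highest signals 20470 and 36430. The size of a list median therefore does not settle its direction. After quantile normalization the camera adjusted p was 0.0015 for matrix, 9.38e-06 for contractile, 1.94e-05 for proliferation and 0.0979 for patterning genes.

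Probe sets of the same gene often differed from each other between depots. Of 1139 genes with several tested probe sets, 191 had all of them past the threshold in 1 direction (147 higher, 44 lower) and 214 had probe sets past it in both directions. Since 51.7% of all tested probe sets passed, part of both counts arises by chance, and their chance level was not computed. Across 1624 such pairs the correlation of the depot difference was 0.0175, against 0.27 for the age difference averaged over depots; genes are not independent replicates. Catenin beta 1 (Ctnnb1) is an example, with -0.78, 1.45 and 0.74. With the 3'/5' ratio as a covariate 274 probe sets passed. The log2 ratio was -0.149 to 0.157 on perirenal and 2.39 to 5.78 on epididymal arrays, so the covariate nearly coincides with depot. This fit carries the slope among the epididymal arrays to the perirenal ratios and loses precision. The 274 are therefore not a count of the differences left after correction for RNA completeness.

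**Figure D3:**
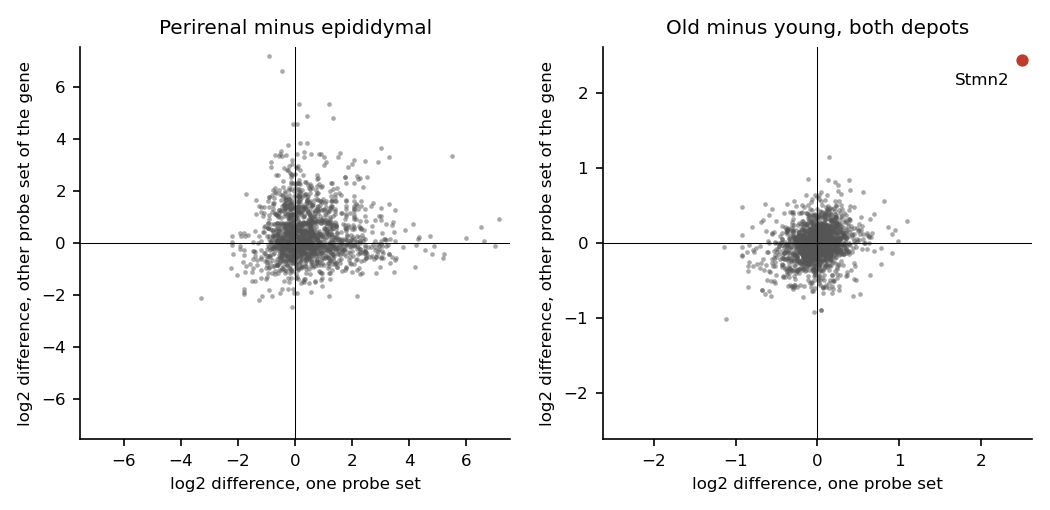
Log2 differences of pairs of probe sets of the same gene (1 point per pair, 1624 pairs), perirenal minus epididymal on the left and old minus young on the right. The depot differences of a pair were nearly uncorrelated (r = 0.0175), while both probe sets of Stmn2 were higher in old rats.

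Depot differences were large at each age. Within young rats the rule took Lyst (fitted log2 difference 5.58 ± 0.72 SE), Il1r1 (4.77 ± 0.62) and Fgf7 (4.61 ± 0.41) as higher in perirenal cells and Tgm2 (-3.75 ± 0.40), Cox6b2, a cytochrome oxidase subunit (-3.66 ± 0.77), and Ptn (-3.64 ± 0.41) as lower, with n = 3 arrays per depot. Of 11106 probe sets 3880 differed, 2223 higher and 1657 lower, and 3927 with the rat as a block. Within old rats it took Vof16 (5.22 ± 0.90), Chpf2 (chondroitin polymerizing factor 2, 4.27 ± 0.74) and Snrk (a sucrose non-fermenting related kinase, 4.23 ± 0.85) as higher, and Olr1 (-4.15 ± 0.43), Smoc1 (a secreted calcium-binding matrix protein, -3.75 ± 0.42) and Scaf1 (-3.59 ± 0.39) as lower. The lower group of Lyst, Il1r1, Cox6b2, Vof16, Chpf2, Snrk, Olr1, Smoc1 and Scaf1 had a geometric mean below the filter level, so the sizes and order of these differences are not well measured. In old rats 3528 differed, 2136 higher and 1392 lower, and 3612 with the block. Past the threshold at both ages were 2509 probe sets, all in the same direction, 1504 higher and 1005 lower, where overlap of independent calls would give 427.5 and 207.7. The calls are not independent, since both ages share the spread of each probe set in the same fit, so these expected counts may be too low. The spike-ins also separated the depots at both ages, so an effect of labelling would recur in this overlap as well. With the 3'/5' covariate 412 passed in young and 32 in old rats. The ratio separated the depots at each age, so these 2 counts also reflect lost precision.

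In perirenal cells, age went with no single gene past the threshold, while macrophage and leukocyte markers were higher as a list. The list had 12 of 14 members above 0 and a median log2 difference of 0.49 (adjusted p = 4.86e-05, and adjusted p = 0.979 with an estimated correlation). Its members with the largest values were Cd68, a lysosomal glycoprotein of macrophages (1.99 ± 0.62 SE, n = 3 arrays per age), Fcgr2b, an Fc receptor (1.59 ± 0.38), Lyz2, the macrophage lysozyme (1.53 ± 0.54), and Fcer1g, the common Fc receptor chain (0.96 ± 0.35). Cd68 had geometric mean signals of 50.6 in young and 201 in old cells, and Lyz2 of 247 and 715. The young Cd68 mean lay below the filter level, so the size of its difference is not well measured. Cd68 signals were 35.5, 169.9 and 21.5 in young and 105.1, 256 and 303 in old perirenal cells, so the groups overlapped. Cd14 (-0.02) and Aif1 (-0.06) lay near 0. None of the 14 passed over all tested probe sets, and 2 passed adjusted over the list alone. Lyz2, Fcer1g, Cd14 and Aif1 lie outside the rule for named genes and were chosen after their values were seen.

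**Figure D4:**
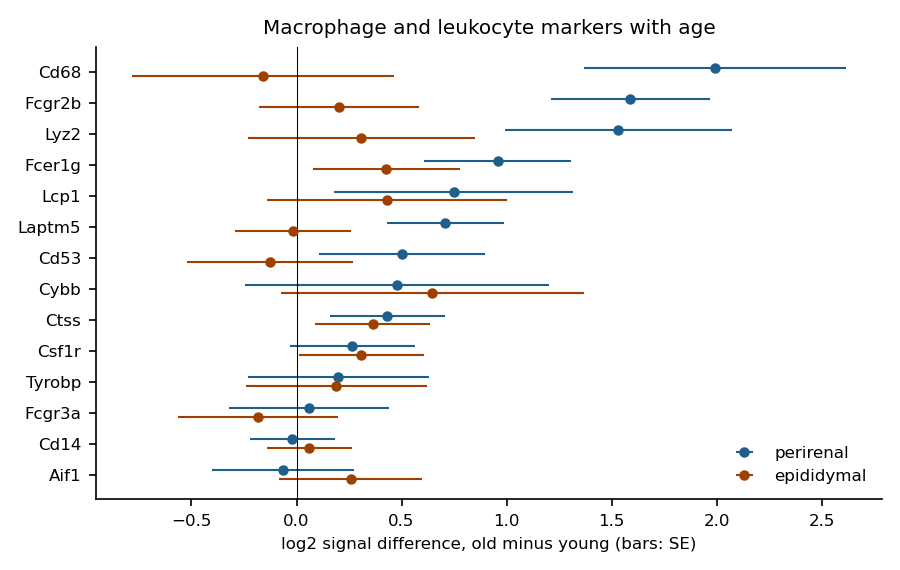
Log2 signal differences, old minus young, with standard errors (bars) for the 14 measured macrophage and leukocyte markers in perirenal and epididymal cells, 3 arrays per age and depot. In perirenal cells 12 of 14 lay above 0 and in epididymal cells 10 of 14.

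The smallest p among single genes in perirenal cells were those of Stmn2, a stathmin that destabilises microtubules in growing nerve processes (2.25 ± 0.39, adjusted p = 0.149, and 2.76 ± 0.44 in its other probe set). RT1-T24-4, a class I histocompatibility gene (1.32 ± 0.23), and Dync1i2, a dynein intermediate chain (0.68 ± 0.12), had the same adjusted p. Values were lower in old cells for Epb41l3, a membrane skeleton protein (-1.25 ± 0.27, 0.42, and -1.26 in its other probe set), and Uchl1, a ubiquitin hydrolase of neurons (-0.90, 0.497). Il6 differed by 1.02 ± 0.48, with geometric means of 1070 and 2174 and no overlap of the groups, which chance gives in 10% of genes for 3 against 3, and an adjusted p of 1.00. Pparg differed by 0.39 ± 0.37, Fabp4 by 0.20 ± 1.04, Ddit3 by -0.05 and Celf1 by 0.06 (0.39 in its other probe set). These 4 values had no settled direction: leaving out 1 array gave -0.02 to 0.72 for Pparg, -0.84 to 1.45 for Fabp4, -0.28 to 0.10 for Ddit3 and -0.03 to 0.20 for Celf1. With limma, 0 of 11106 probe sets passed, and 486 had an unadjusted p under 0.05. This is fewer than the share of 0.05 expected without any age difference. The other 21 tested lists did not pass, and the inflammatory list came nearest (adjusted p = 0.0744). Array weights gave 7 probe sets, the perirenal arrays alone gave 1, and leaving out perirenal young 2 gave 2.

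In epididymal cells, Stmn2 rose with age 6.24-fold (log2 difference 2.64 ± 0.39 SE, n = 3 arrays per age, adjusted p = 0.0379), from a geometric mean signal of 74.0 to 461, and its other probe set differed by 2.24 ± 0.44 (adjusted p = 0.108), a size not well measured, as its young signals lay below the filter level. Cd55, which protects cells from complement, rose by 1.23 ± 0.20 (0.0465), with 0.97 in its other probe set. Pnisr, a serine and arginine rich nuclear protein, fell (-1.25 ± 0.19, 0.0388), as did B3gat3, an enzyme of proteoglycan linker synthesis (-1.25 ± 0.21, 0.0465), Resf1, a retroelement silencing factor (-1.02 ± 0.17, 0.0465), and Sh3gl1, the endocytic protein endophilin A2 (-0.90 ± 0.14, 0.0441). A pair of probe sets without a symbol completed the 8 that passed, 2 higher and 6 lower, with 927 at an unadjusted p under 0.05. Among genes that did not pass were Rxra (-1.68 ± 0.34, adjusted p = 0.12, with an old mean below the filter level), Tgfbi, a matrix protein induced by TGF-beta (-1.58 ± 0.41, 0.291), Il6 (0.76 ± 0.48, 0.703), Pparg (-0.19, and 0.02 without old 3), Fabp4 (-1.05 ± 1.04, with an old mean below the filter level), Ddit3 (-0.25 ± 0.33, and 0.20 without young 1) and Celf1 (0.17 ± 0.16, and 0.66 in its other probe set).

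As lists in epididymal cells, proliferation and cholesterol synthesis genes were higher and oxidative phosphorylation and interferon genes lower in old rats by camera at the preset correlation, by small amounts. None of these 4 calls held, at adjusted p = 0.86 with an estimated correlation. Of 44 proliferation genes 35 lay above 0 with a median of 0.13 (adjusted p = 0.022), such as Mybl2, a cell cycle transcription factor (0.74), while the proliferation antigen Mki67 was at -0.60. Of 19 cholesterol genes 15 lay above 0 with a median of 0.23 (0.0225), such as Cyp51, the lanosterol demethylase (0.60, and 0.28 in its other probe set). Of 45 oxidative phosphorylation genes 14 lay above 0, with a median of -0.11 (0.0296), and the subunits Cox5b (-0.60 ± 0.11, adjusted p = 0.108) and Ndufa5 (-0.52) were among the lower ones. Of 32 interferon genes 8 lay above 0, with a median of -0.16 (0.0296). No member passed over all tested probe sets, and adjusted over the list alone only 1 oxidative phosphorylation gene, which fell, did. The other 18 tested lists did not pass.

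Which epididymal age results passed depended on single arrays and settings. The Stmn2 difference itself was 2.13 to 2.98 with 1 array left out, but did not pass after quantile normalization (2.48, adjusted p = 0.0795) or without old 2 (2.98, 0.0623), young 2 (2.71, 0.157) or young 3 (2.78, 0.103). The epididymal arrays differed in their beta-actin 3'/5' ratio within each age, 5.25, 10.2 and 38.2 in young and 7.0, 13.9 and 55.0 in old rats. Krt8, a keratin, had signals of 79.6, 543 and 556 in young 1, 2 and 3, and of 44.9 to 122 on the other 9 arrays. Its age difference was -1.92 ± 0.61 (adjusted p = 0.4), and -2.85 (0.0196) without young 1. Slpi, a secreted protease inhibitor chosen after its values were seen, had signals of 898, 7210 and 7036 in young and 2258, 2463 and 5269 in old epididymal cells. The 8 measured mesothelial markers had no call as a list with age in epididymal cells (median -0.03, adjusted p = 0.819). The count was 0 after quantile normalization, with array weights or with the epididymal arrays alone, 2 without the 2 arrays with the highest ratio, 2 with the floor, 1 without the intensity trend, and 5 without the filter. It was 14 without old 1, 0 without old 2, 19 without young 1, 0 without young 2 and 1 without young 3. Without epididymal young 1 the proliferation list was lower in old rats (adjusted p = 0.00839) and the cholesterol list had no call (0.557), and each of the other calls was lost without at least 1 array: oxidative phosphorylation without old 1 (0.245), old 2 (0.155) or young 3 (0.922), interferon without old 2 (0.155), old 3 (0.259), young 2 (0.0722) or young 3 (0.115). The proliferation call was also lost without old 2 (0.155) or old 3 (0.341), and the cholesterol call without old 2 (0.0954) or old 3 (0.341). The interferon call was lost after quantile normalization (0.105), without the filter (0.0976) and without the 2 arrays with the highest ratio (0.315), where the oxidative phosphorylation list turned upward with no call (0.939).

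Averaged over depots, Stmn2 rose with age 5.44-fold. Its brighter probe set (2.44 ± 0.21 SE, n = 3 rats per age, adjusted p = 0.00809) and its other one (2.50 ± 0.28, adjusted p = 0.0324, with young epididymal signals of 33.3, 28.9 and 21.7, below the filter level) were the only 2 of 11106 that passed with limma, both higher in old rats, and 647 had an unadjusted p under 0.05. The log2 signal of the brighter one was 8.89 ± 0.574 (SD, n = 3) in young and 11.14 ± 0.317 in old perirenal cells, and 6.21 ± 0.354 in young and 8.85 ± 0.896 in old epididymal cells. The lowest old array lay above the highest young array within each depot. The count was 2 with the rat as a random block, 0 without an intensity trend, 0 without young rat 2, young rat 3 or old rat 1, and 1 without old rat 3. For the brighter Stmn2 probe set the difference stayed between 2.22 and 2.67 with any 1 rat left out, and in the 3 cases with a count of 0 it was 2.33 (adjusted p = 0.0608), 2.51 (0.0516) and 2.44 (0.0576). The count was also 1 without the filter, with the filter at 50% and without the 2 rats whose arrays had the highest 3'/5' ratio.

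**Figure D5:**
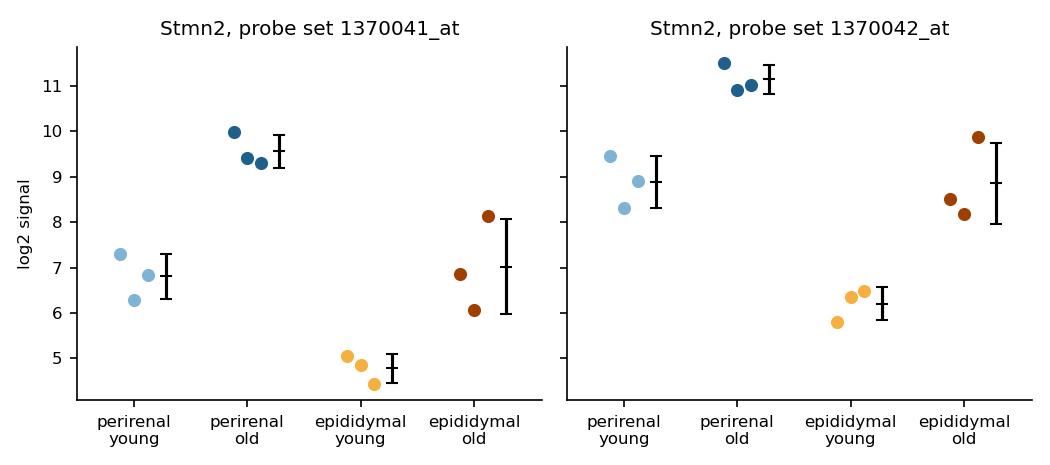
Log2 signal of both Stmn2 probe sets on each of the 12 arrays by depot and age (points), with the mean and SD of each group (bars, n = 3). Old arrays lay above young arrays in each depot, and at each age the perirenal group mean lay above the epididymal one.

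Averaged over depots, 4 lists passed camera at the preset correlation, each with an adjusted p = 0.818 with an estimated correlation. Macrophage markers (13 of 14 above 0, median 0.37, adjusted p = 0.00061), proliferation genes (34 of 44, 0.18, 0.00266) and cholesterol synthesis genes (16 of 19, 0.15, 0.0313) were higher in old rats. Oxidative phosphorylation genes were lower (14 of 45 above 0, median -0.07, adjusted p = 0.0101). No member passed over all probe sets or adjusted over the list alone, and the other 18 tested lists did not pass. Without young rat 1 the proliferation (0.341) and cholesterol (0.678) lists turned lower with no call. Calls were lost without old rat 2 (macrophage 0.103, proliferation 0.229, oxidative phosphorylation 0.229, cholesterol 0.196), without old rat 3 (proliferation 0.0556, cholesterol 0.294), without young rat 3 (macrophage 0.0804, oxidative phosphorylation 0.585) and without old rat 1 (oxidative phosphorylation 0.159). Leaving out both rats with the highest 3'/5' ratios ended those of macrophage (0.679), oxidative phosphorylation (0.972) and proliferation genes (0.0523), and quantile normalization (0.067) or the 3'/5' covariate (0.129) that of cholesterol synthesis.

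Whether age acted differently in the depots was tested by the interaction. The genes with the smallest p were Smoc1, whose geometric mean went from 136 in young to 42.9 in old perirenal cells and from 220.1 to 578 in epididymal cells (log2 difference of the age effects -3.05 ± 0.59 SE, n = 3 arrays per group), and RT1-T24-4 (1.44 ± 0.32), both with an adjusted p of 0.84. Interferon and antigen presentation genes had a more positive age difference in perirenal than in epididymal cells in 27 of 32, with a median of 0.23 (adjusted p = 0.0282, and adjusted p = 0.76 with an estimated correlation). With the rat as a block it was 0.0246. No member passed over all tested probe sets or adjusted over the list alone, and the other 21 tested lists did not pass. With limma, 0 of 11106 probe sets passed, 0 also with the rat as a fixed block, and 612 had an unadjusted p under 0.05. Across probe sets the age differences of the depots had a correlation of 0.0708. The interferon call was lost without perirenal young 1 (0.123), perirenal old 3 (0.317), epididymal old 2 (0.0701) or epididymal old 3 (0.121), with the 3'/5' covariate (0.0503), without the 2 arrays with the highest ratio (0.0611) and without the filter (0.155). Without those 2 arrays the age difference of macrophage genes was higher (0.0015) and those of cholesterol synthesis (0.00975) and proliferation genes (0.0198) lower in perirenal than in epididymal cells. The estimated correlation was not run without these arrays, and with all arrays each of the 3 lists had an adjusted p = 0.982 with an estimated correlation.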

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

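Chosen only after the result was seen were the tests of further probe sets of the same genes, of the spike-ins and of the 3'/5' ratio as a covariate for Stmn2. When the neuronal and the second macrophage list were written, the values of their members Uchl1 and Mmp12 in perirenal cells had been seen.

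Some control probe sets, which no comparison used, separated the depots. Some 3'/5' ratios overlapped: that of the control cre was 1.13 to 1.43 on perirenal and 1.24 to 1.73 on epididymal arrays. That of the control bioD was 1.36 to 2.16 and 1.34 to 1.79. The 3' signal of bioD nevertheless separated the depots, at 2194.8 to 2935.1 on perirenal and 3420 to 4942.5 on epididymal arrays. On the epididymal arrays the mean signals of the bacterial poly(A) controls were 645 for dap, 97.5 for lys, 188 for phe and 276 for thr, and every one of the 6 arrays lay above every perirenal array. The median beta-actin 3'/5' ratio of the epididymal arrays was 12.1, and again every one lay above every perirenal array. The interferon and antigen presentation list had an age difference that differed between depots by the interaction test at the preset correlation (adjusted p = 0.0282), a call lost at adjusted p = 0.76 with an estimated correlation and at 0.155 without the filter.

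The first pattern is the 5738 probe sets that differed between depots, a count that 1 of 100 splits within the ages reached, the real one (highest other 1358), and 1 of 32 swaps of arrays within rats (highest other 246), so chance can be excluded. Loss of 5' signal on the epididymal arrays may account for part of it: across probe sets the slope of the signal on the log2 beta-actin ratio among the epididymal arrays correlated with the depot difference at r = -0.317 (rho -0.209), and the median slope was -0.43 for the 86 probe sets with a perirenal excess over 3 on the log2 scale. It was -0.0738 for the 1078 with a perirenal excess of 1 to 2, and -0.0112 for the 4763 with one of 0 to 1. Probe sets higher in epididymal cells had median slopes near 0: 0.0129 for 4514 differing by up to 1, 0.0227 for 387 by 1 to 2, and 0.00853 for 41 by 2 or more. The other probe sets of genes with a perirenal excess over 2-fold were higher there in 53.1% of 612 (95% exact binomial interval 49.1 to 57.1), against 55.5% of all tested. Those of genes with an epididymal excess were higher there in 52.5% of 118 (43.1 to 61.8), against 44.5%. The interval for these 118 spans 44.5% as well as far higher shares, so it decides neither for nor against 5' loss in these genes. The intervals here treat probe sets and pairs as independent, which they are not, so they are too narrow. Whether 5' loss accounts for every call stays open, since called pairs of 1 gene had opposite signs in 42.3% of 600 (38.3 to 46.4), against 48.5% of random pairs. The poly(A) controls had mean signals of 1.08 to 41.1 on perirenal arrays, and 0 of 6 perirenal arrays reached the lowest epididymal dap signal. Controls added before labelling thus differed between the depots. Their summed 3' to 5' ratio was 5.13 to 12.85 on epididymal arrays, against 0.798 to 2.88 at the low perirenal signals. RNA that did not come from the cells thus also had less 5' than 3' signal on the epididymal arrays. How much of the depot difference came from labelling cannot be told apart from depot, and a difference between the cells of the depots stays open as untested.

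The second pattern is the higher Stmn2 signal in old rats of both depots. Neurons carried over into the cultures would raise other neuronal markers. The 13 measured of 28 had a median age difference of -0.0866, 6 of them lay above 0, and 0 differed by more than 1 on the log2 scale. Thy1 (5270) and Tubb3 (615 in young perirenal cells) were so abundant that a small share of neurons would not show in them. The other measured markers argue against a share of neurons large enough to move them, and a smaller share stays open. Unequal 3'/5' ratios are argued against by the fit with the ratio as a covariate, in which the difference was 2.46 (adjusted p = 0.0265, against 0.0045 to 0.0608 when each rat was left out). A true age difference in these cells is consistent with both tests and remains a hypothesis, found and tested on the same 6 rats. The average over depots allows 10 splits of the rats, too few for a share under 0.05 (2 calls in the real split, 1 in the highest other).

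The third pattern is the macrophage list in old perirenal cells. A single array does not account for it, since the lowest list median without 1 array was 0.39, without perirenal young 1, against 0.49 with all arrays. More macrophages in the old cultures may account for it: of 24 measured members of a second list, which shares no gene with the first, 66.7% lay above 0, with an unadjusted camera p of 0.0179 and an unadjusted p of 0.0997 with an estimated correlation. Its larger differences were those of Mmp12 (1.44 ± 0.55) and Casp1 (0.91 ± 0.20), whereas the abundant members Lgals3 (-0.20), Capg (-0.01), Ctsk (0.05) and Cyba (0.00) had geometric mean signals from 2800 up to 9210 in all 4 groups, where a small share of macrophages would not show. Abundance does not explain the members with low signals that lay below 0. Among these were Acp5 (-0.47 ± 0.34, geometric means of 246 in young and 178 in old perirenal cells), Ccl4 (-0.42 ± 0.32, 203 and 152) and Cx3cr1 (-0.31 ± 0.43, 115 and 92.7). The labels state that macrophage markers did not differ with age or depot, and a change in the preadipocytes themselves stays open as untested.

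Other comparisons of 3 arrays against 3 allow only 10 splits, too few for a share under 0.05. The counts were 3880 in the real split and 0 in the highest other for depot in young rats, 3528 and 0 for depot in old rats, 0 and 1 for age in perirenal cells, and 0 and 1 for the interaction. For age in epididymal cells they were 8 and 29, and 2 of the 10 splits reached the real count. The split with 29 parted the 3 epididymal arrays with the lowest 3'/5' ratios from the 3 with the highest, which points to a structure of these arrays, and with the ratio as a covariate age gave 8, 4 higher and 4 lower, of which 5 were among the 8 without it.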

How the results depend on the processing

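The alternatives with the 3'/5' covariate, without the 2 arrays of the highest ratio and with genes called by all their probe sets, and those that left out arrays for lists and named genes, were chosen after seeing the data. The depot count averaged over ages stayed within 1.5 times of 5738 in all alternatives set beforehand (3967 with 1 probe set per gene to 6933 without a filter). It was 274 with the covariate and 191 for genes with several probe sets all called one way, and 4848 to 5163 without 1 rat. In young rats it was 2560 with 1 probe set per gene, 412 and 108 (covariate, all one way), and 2846 to 3488 without 1 array. In old rats it was 2332, 32 and 82, and 2383 to 3028. Fewer items tested lower the counts of 1 probe set per gene. The covariate nearly coincides with depot, so its depot counts also reflect lost precision. With the rat as a fixed block the counts were 5754, 3927, 3612 and 0 (interaction), and as a random block 6013, 4209, 3923, and then 0, 6, 2 and 0 for age in perirenal cells, in epididymal cells, averaged, and the interaction.

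Age in perirenal cells gave 7 with array weights, 1 with the perirenal arrays alone and 0 to 2 without 1 array. Age in epididymal cells gave 0 after quantile normalization, with array weights, with the epididymal arrays alone and for genes called all one way, 2 with the floor, 5 without a filter, 1 without the trend, 2 without the 2 arrays and 0 to 19 without 1 array. Age averaged over depots gave 1 without a filter, with the 50% filter, per gene, without the 2 rats and for genes called all one way, 0 without the trend and 0 to 2 without 1 rat. The interaction gave 0 to 1 without 1 array, the 1 without epididymal young 1. The causes were not tested. Among lists with a call in the main fit, 5 values reversed. Proliferation did so in epididymal cells without young 1 (camera adjusted p 0.00839, range 1.47e-08 to 0.341 over all arrays left out) and averaged without young rat 1 (0.341, range 2.73e-11 to 0.341). Cholesterol synthesis did so likewise (0.557, range 5.24e-05 to 0.557, and 0.678, range 1.09e-05 to 0.678), and oxidative phosphorylation in epididymal cells without the 2 arrays (0.939). Lists without a call in either fit changed direction in 15 values without the 2 arrays, 11 without the filter, 6 after quantile normalization, 5 with the covariate and 2 with the fixed block. Of 236 values of named genes, 214 kept direction and side of the threshold after quantile normalization and 232 without the filter. Of 110 list values, 94 did so with the estimated correlation and 100 with the covariate. The fit on only the groups compared was not run for the average over ages, where it equals the fit of all arrays. Probe sets near the filter level of 56.3 have signals too close to background for a firm ratio.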

Other observations

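These values were chosen only after they were seen: they are genes with several tested probe sets all past the threshold in 1 direction between depots. With 51.7% of all tested probe sets past the threshold, such agreement also arises by chance. Its chance level was not computed, so it does not by itself set these genes apart. Higher in perirenal cells were Htr2a, a serotonin receptor (log2 differences 1.74 to 2.53 over 3 probe sets), Kitlg, the ligand of the Kit receptor (1.53 and 2.72), Cd44, the hyaluronan receptor (1.62 and 1.84), and Aqp1, a water channel (1.86 and 2.92). Stmn2 was also higher in perirenal cells (2.28 and 2.49), on top of its difference with age. Lower in perirenal cells were Cdh2, which codes for N-cadherin (-2.04 and -1.23), Map4, a microtubule-associated protein (-1.76 and -1.12), Cux1, a homeobox repressor (-1.46 and -1.42), and Hif1a, the oxygen-responsive factor (-1.83 and -0.72). The beta-actin 3'/5' ratio (0.902 to 1.11 against 5.25 to 55.0) separated the same arrays. With the largest adjusted p of any of their probe sets, these ran from 4.05e-06 (Map4) to 0.00213 (Htr2a).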
